A study of Mus musculus with 22 samples.

How the data were processed

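Back skin from K14-DN-Clim transgenic mice and wild-type littermates was profiled on 22 single-colour oligonucleotide arrays. DN-CLIM is a dominant-negative form of the CLIM (Ldb) cofactors, nuclear proteins that bind LIM domain factors, and the keratin 14 promoter directs it to basal keratinocytes. Per the labels' protocols, total RNA of back skin from mice of the CB6F1 strain was extracted with TRIzol, cleaned on RNeasy columns and labelled with biotin by in vitro transcription. Per the series' design text, the ages stand for initial hair follicle growth (P6 and P14) and the first resting phase, telogen (P23), with separate mice in each group. Each array's group and replicate number came from its title. There were 5 wild-type and 5 transgenic arrays at P6, 3 and 3 at P14, and 3 and 3 at P23. The labels do not tie an array to a single mouse. The p-values rest on the spread between arrays within groups, estimated in common over the 6 groups. The SD of the log2 difference between 2 arrays of a group ran from 0.265 (transgenic P23) to 0.605 (transgenic P6). The common estimate need not match the spread of the groups compared.

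The deposited table holds 1 intensity (MAS5 signal, linear scale) per probe set and array. MAS5 was used by the authors, per the submitters' processing notes, with its version not given in the sources used here. The deposited intensities were all above 0, and the 2% trimmed mean lay between 500.2 and 500.3 on every array, so each array had been scaled to one trimmed mean. No detection calls were used here. All 22 columns of the table belonged to a sample. The number of arrays, not depth, limits the precision, and dim probe sets are the noisiest.

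The table has 12488 probe sets, 66 of them array controls, which were left out. The platform annotation pairs 10855 probe sets with 1 gene, 396 with several genes and 1237 with none. For 10839 the symbol was looked up through the Entrez identifier in a RefSeq gene table, and 0 symbols changed. No gene was named from a probe set with several genes or none. Signals were used as log2 values with no further normalization, because the array medians (7.56 to 7.80, log2) differed by less than the limit of 0.3 set in advance. Probe sets were tested where the mean over all 22 arrays was at or above the median of these means (log2 7.67, a signal of 203). That left 6211 probe sets, 5637 of them with 1 gene, for 4900 genes. Within groups the mean correlation of an array's log2 signals with the others of its group ranged from 0.923 (transgenic P6 replicate 5) to 0.982. No 2 arrays held identical values.

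limma 3.58.1 in R 4.3.3 was fitted to all 22 arrays with 1 mean per group, since the 6 groups are one tissue on one array type and share an estimate of the spread. Moderated tests used eBayes with a trend of the variance on signal, and Benjamini-Hochberg adjustment over the 6211 probe sets with a threshold of 0.05. The contrasts were transgenic minus wild type at each age and averaged over the 3 ages, P14 minus P6 and P23 minus P14 in wild type, and the differences of the genotype effect between ages. log2 changes are given with their standard errors (SE), and group levels as mean log2 signal with the SD over arrays.

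There were 27 gene lists (hair, epidermal, dermal, immune, vascular, muscle and other cell types, and pathways). They were tested with camera (preset correlation 0.01) on 1 probe set per gene, that with the highest mean signal, where at least 5 members were tested. The T cell list (1 tested member, Thy1) and the list of sex-linked genes (0 tested members) were too short, which left 25. Each list was run again with camera's estimated correlation and with fry. Members were counted past the threshold over all probe sets and also adjusted over the list alone. The named genes were, for each comparison, up to 10 largest rises and 10 largest falls past the threshold whose groups did not overlap, up to 5 members of each list with the smallest p, and Ldb1, Ldb2, Lhx2, Cd34, Krt14 and Krt15. Of these the text names a selection. Lhx2 had no tested probe set. The Krt14 and Krt15 probe sets were dim (19.1 and 1.4 as percentiles of mean signal) and were not tested. Sncg, Npnt over the 3 ages, Arg1, Rflnb, Meg3 over the 3 ages, Slc29a1, Nrep, and Sft2d1 and Fst in the contrasts between ages fall outside this rule and were named after their values were seen. The samples, tests, gene lists, naming rule and all but the last of the alternatives below were fixed before the data were examined.

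The fit was tested on simulated data drawn from the real means and spreads of the 6211 probe sets, with 200 of them changed. Each probe set had the same simulated spread in all groups. Recovery depends on how many probe sets are changed. The genotype contrasts at P6, P14, P23 and over the 3 ages called 2, 4, 10 and 11 in the real data. Where fewer than 200 are changed, recovery may be lower than the shares below. At a log2 change of 1 it recovered 89.6% for the contrast at P6, 83.6% at P14, 88.1% at P23 and 98.5% over the 3 ages. At a log2 change of 0.5 it recovered 58.2%, 22.4%, 23.9% and 79.1%. For wild type it recovered 89.6% (P14 against P6) and 86.6% (P23 against P14) at a change of 1. For the differences between ages at a change of 1 it recovered 73.1% (P14 against P6), 59.7% (P23 against P14) and 64.2% (P23 against P6). camera called a simulated list of 16 genes shifted by 0.5 at each of the 6 contrasts where lists were tested. Of the other 24 lists it called 0. The simulated genes varied independently of each other, so this run cannot show how the preset correlation fares with correlated genes.

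Alternatives were quantile normalization, a shift to equal medians, no filter, a stricter filter (at or above the 75th percentile), an offset of 46.9 (the 25th percentile of the signals) before log2, eBayes without the trend, array weights, 1 probe set per gene, a block for the replicate number, sex class as a covariate, only the groups compared, and leaving out each array in turn. The sex class was read from Xist and Eif2s3y signals. Treating the P6 arrays numbered 1 to 3 and 4 to 5 as 2 batches, and fitting each of these alone, was chosen after seeing the data.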

Results

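Transcript levels in back skin were compared between K14-DN-Clim transgenic mice, in which a dominant-negative CLIM protein is expressed from the keratin 14 promoter, and wild-type littermates. The 22 arrays covered postnatal days 6 and 14, when the first hair follicles grow, and postnatal day 23, the first resting phase. There were 5 arrays per genotype at P6 and 3 per genotype at P14 and at P23. The design asks how blocking CLIM in basal keratinocytes changes gene expression in skin at these stages. The 20 brightest probe sets held 6.2 to 10% of the signal at P6 and P14 and 4.3 to 5% at P23.

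Ldb1 and Ldb2, the genes of the CLIM cofactors, showed no difference past the threshold between the genotypes at any age. The log2 difference of Ldb1, transgenic minus wild type, was 0.30 at P6, -0.05 at P14 and 0.08 at P23, with adjusted p = 0.534, 0.984 and 0.999 in limma. That of Ldb2 was -0.09, 0.14 and -0.01, with adjusted p = 0.843, 0.931 and 0.999. The Ldb1 difference turned to 0.06 and 0.05 at P14 without transgenic replicate 2 or 3 and to -0.02 at P23 without wild-type replicate 2. The Ldb2 difference at P23 turned to 0.09 without wild-type replicate 2 and 0.10 without transgenic replicate 3. Which part of the messenger RNA the transgene shares with the Ldb1 probe set is not given in the sources used here, so this level does not check the labels. Lhx2, a LIM homeobox gene of the hair follicle, had no tested probe set.

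At P6 the gene for basonuclin 1, a zinc finger protein of basal keratinocytes, was lower in transgenic skin. Bnc1 fell 1.58-fold (log2 change -0.66, SE 0.10, adjusted p = 0.0055 in limma), from a mean log2 signal of 9.28 ± 0.11 (SD, n = 5) to 8.61 ± 0.13 (SD, n = 5). Each of the 5 transgenic arrays lay below each of the 5 wild-type arrays. The gene for gamma-synuclein, Sncg, fell 2.7-fold at the probe set that passed (log2 change -1.43, SE 0.23, adjusted p = 0.0071 in limma). Another tested Sncg probe set had a higher mean signal and did not pass. The one that passed therefore lies outside the naming rule and was chosen after its values were seen. The Bnc1 and Sncg probe sets were the only 2 of 6211 past the threshold, with 508 at an unadjusted p under 0.05 against 311 given by chance.

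Among the gene groups at P6, those of the hair shaft, blood and dermis lay lower in transgenic skin, and those of muscle and the differentiated epidermis lay higher, none of them past the threshold with an estimated correlation (adjusted p = 0.51 to 0.61). No single member passed the threshold over all probe sets. All 10 hair shaft keratins were lower (median log2 difference -0.22, camera adjusted p = 0.01), among them Krt83 at -0.36 and Krt81 at -0.26. All 7 erythroid genes were lower (median -0.32, adjusted p = 0.018), with Alas2, the first enzyme of heme synthesis in red cells, at -0.37. Of 29 dermal matrix genes 23 were lower (median -0.10, adjusted p = 0.018), and Ogn (osteoglycin, -0.57) was past the threshold adjusted over the list alone. Of 14 cholesterol synthesis genes 12 were lower (median -0.15, adjusted p = 0.033), and 27 of 37 cell cycle genes were lower (median -0.07, adjusted p = 0.044), with Rrm2 at -0.49 and Cks1b at -0.25. Of 26 skeletal muscle genes 20 were higher (median 0.15, adjusted p = 0.01), with Myh8, the perinatal myosin, at 0.45 and Acta1 at 0.35. Of 22 immediate early and heat shock genes 18 were higher (median 0.11, adjusted p = 0.033), with Egr2 at 0.30. Of 21 epidermal differentiation genes 14 were higher (median 0.08, adjusted p = 0.033). Adjusted over the list alone, 4 of them passed as higher, namely Calm4 at 0.38, loricrin (Lor) at 0.44, Krtdap at 0.31 and Krt1 at 0.41, and 1 as lower. With an estimated correlation none of the 8 lists passed: adjusted p = 0.61 for dermal matrix and 0.51 for each of the other 7 with an estimated correlation.

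Genes of the basal layer went both ways at P6. Of 13 genes of basal keratinocytes and the hemidesmosome, the junction that anchors these cells, 0 passed over all probe sets in limma and 4 adjusted over the list alone. Col17a1, the transmembrane collagen of that junction, was lower (-0.36), and Itgb4 (0.51), Plec (0.89) and Lamb3 (0.33) were higher; the list had adjusted p = 0.13. Scd1, a desaturase of sebaceous glands, was at -0.62 (adjusted p = 0.092), and 5 of the 7 sebaceous genes were lower. Krtap5-4 and Krtap14, keratin-associated proteins of the hair shaft, were at -0.46 and -0.44, and Cd93, an endothelial receptor, at -0.35. Lmo4, a LIM-only partner of CLIM, was at -0.31 (adjusted p = 0.56), and without transgenic replicate 5, whose level was apart from the other 4, its adjusted p was 0.0043. Of the 25 lists tested at P6, that of macrophages and antigen presentation had a median of 0.02 and a mean of -0.05.

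The count at P6 was 4 without transgenic replicate 1 or 4 and 5 without transgenic replicate 5. Bnc1 and Sncg passed with any 1 array left out but not with the sex class as a covariate, where the adjusted p of both was 0.07 (log2 changes of -0.65 and -1.37) and the count 0, nor in a fit of only these 10 arrays (0.12 and 0.31). The 10 arrays also parted by number: those numbered 4 and 5 differed from those numbered 1 to 3, over both genotypes, at 345 probe sets, a contrast chosen after seeing the data. With that split as a batch term 3 probe sets passed, and within arrays 1 to 3 and within arrays 4 and 5 there were 5 each. Within these batches the adjusted p of Bnc1 was 0.12 and 0.092. The number of lists past the threshold was 8 with the batch term, 1 within arrays 1 to 3 and 3 within arrays 4 and 5, and it was 4, 5, 5 and 1 without wild-type replicate 2, wild-type replicate 3, transgenic replicate 2 and transgenic replicate 4. Each of the 8 lists did not pass without at least 1 array, in 1 (erythroid, 0.063 without transgenic replicate 3) to 7 (cell cycle, up to 0.18) of 10 runs. Without transgenic replicate 5, which lay apart from its group, the dermal matrix (0.32), cell cycle (0.15), cholesterol (0.11) and immediate early (0.09) lists did not pass, and the cholesterol list did not pass in 6 of 10 runs. In arrays 4 and 5 the epidermal differentiation list was lower in transgenic skin (adjusted p = 0.67).

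**Figure D1:**
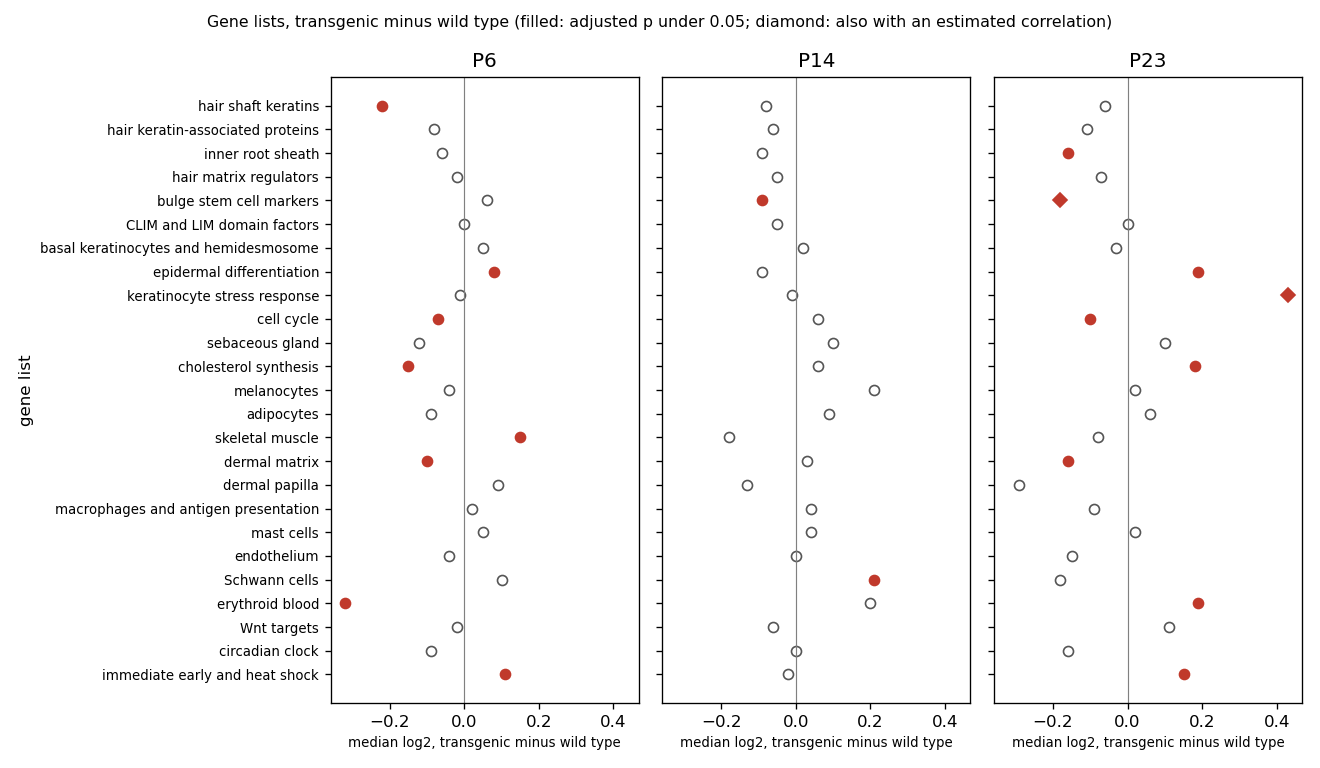
Median log2 difference, transgenic minus wild type, of the members of each gene list (1 point per list) at P6, P14 and P23; filled points passed camera at an adjusted p under 0.05 with the preset correlation, and diamonds also with an estimated one. The keratinocyte stress response list lay at 0.43 at P23 and at -0.01 at P6 and P14, and the bulge list at -0.18 at P23.

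At P14 the collagen XVII gene was lower in transgenic skin, and the imprinted noncoding RNA Meg3 and the vesicle transport gene Sft2d1 were higher. Col17a1 fell 1.54-fold (log2 change -0.62, SE 0.11, adjusted p = 0.015 in limma), from 11.28 ± 0.01 (SD, n = 3) to 10.66 ± 0.14 (SD, n = 3). Sft2d1 rose 2.54-fold (log2 change 1.34, SE 0.22, adjusted p = 0.015), from 10.60 ± 0.09 to 11.95 ± 0.09 (SD, n = 3 each). Meg3 rose 5.59-fold at 1 probe set (log2 change 2.48, SE 0.35, adjusted p = 0.003), where the wild-type arrays were widely spread (7.68 ± 1.12 against 10.16 ± 0.45, SD, n = 3 each). That SE comes from the spread common to all groups, not from the P14 arrays alone. The other Meg3 probe set gave 0.29 (SE 0.17, adjusted p = 0.83). For all 3 genes each transgenic array lay on the same side of each wild-type array. A probe set shared by several genes also passed (0.82), which made 4 probe sets, 3 higher and 1 lower, with 389 at an unadjusted p under 0.05 against 311 given by chance.

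Of 16 markers of the bulge, the stem cell compartment of the follicle, 11 were lower at P14 (median -0.09, camera adjusted p = 0.027, but adjusted p = 0.12 with an estimated correlation). Col17a1 fell, 15 did not pass, and adjusted over the list alone 1 was higher and 4 lower. These were Sfrp1 (0.69), a secreted Wnt inhibitor, and Col17a1, the Wnt receptor gene Fzd2 (-0.59), S100a4 (-0.56) and Ccn2 (-0.57), a matricellular growth factor. All 6 Schwann cell genes were higher (median 0.21, adjusted p = 0.015, and adjusted p = 0.13 with an estimated correlation), with Ncam1 at 0.61 (adjusted p = 0.0797). Lmo4 was at -0.62 (adjusted p = 0.22). Of 5 dermal papilla genes 0 passed in limma over all probe sets and 3 adjusted over the list alone, with Igfbp3 at -0.75, Sox18 at -0.42 and Vcan at 0.55. Further genes apart from wild type without passing were Aurkb, a mitotic kinase, at 1.78 (adjusted p = 0.118), Krtap13 at 0.71, the melanocyte enzyme gene Dct at 0.68, Mylpf of muscle at 0.50, the clock-controlled Tef at -0.40 and Gata3 of the inner root sheath at -0.34. Cd34, a bulge surface marker, was at -0.43 (adjusted p = 0.812).

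The count at P14 was 1 without wild-type replicate 2, 0 without wild-type replicate 3, 2 without transgenic replicate 2 and 9 without transgenic replicate 3. Meg3 had adjusted p = 0.057 without wild-type replicate 3. Sft2d1 did not pass without wild-type replicate 1, 2 or 3 or transgenic replicate 2 (up to 0.095), nor Col17a1 without wild-type replicate 1, 2 or 3 or transgenic replicate 1 (up to 0.094). In a fit of only these 6 arrays, Meg3 (0.22) and Col17a1 (0.18) did not pass, and with the replicate number as a block Col17a1 had 0.11. The bulge list did not pass without wild-type replicate 1 or 3 or transgenic replicate 1 or 3 (up to 0.19), nor the Schwann list without wild-type or transgenic replicate 3 (up to 0.11). Of the 10 splits of these 6 arrays, the real one included, 7 gave at least 2 lists past the threshold.

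At P23, in resting skin, the keratinocyte stress response list was higher in transgenic skin, and bulge markers and Gli1 were lower. In wild type this list also changed with age, by a median of -1.22 (log2) from P14 to P23. Sprr1a, a precursor of the cornified envelope, rose 2.11-fold (log2 change 1.08, SE 0.17, adjusted p = 0.009 in limma), and Krt16, a keratin of wounded and hyperproliferative epidermis, rose 3.23-fold (log2 change 1.69, SE 0.32, adjusted p = 0.024). Gli1, the transcription factor at the end of the hedgehog pathway, fell 2.49-fold (log2 change -1.32, SE 0.21, adjusted p = 0.009). Fst, which encodes the activin antagonist follistatin, fell 2.11-fold (log2 change -1.07, SE 0.18, adjusted p = 0.009). Npnt, the basement membrane protein nephronectin, fell 1.91-fold (-0.94, SE 0.16, adjusted p = 0.017), and Bnc1 fell 1.59-fold (-0.67, SE 0.13, adjusted p = 0.024). The carbonic anhydrase gene Car12 (0.77, adjusted p = 0.017) and Aebp2 (0.55, adjusted p = 0.024), a partner of polycomb repressive complex 2, rose, and the hair gene Krtap3-1 (-0.91, adjusted p = 0.047) fell. For each of these 9 genes all 3 transgenic arrays lay on the same side of all 3 wild-type arrays. With a probe set of several genes (0.76), 10 probe sets passed, 5 higher and 5 lower, with 284 at an unadjusted p under 0.05, fewer than the 311 given by chance.

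The keratinocyte stress response and bulge lists were the 2 that passed at P23 both with the preset and with an estimated correlation. Of the 16 stress response genes 13 were higher (median 0.43, camera adjusted p = 4.6e-10, and adjusted p = 0.01 with an estimated correlation); 2 rose, 0 fell and 14 did not pass, and 7 were higher adjusted over the list alone. Beside Sprr1a and Krt16 these included Krt17 (0.51), Krt6b (0.52) and Sprr2i (0.42). The list's mean was at least 9.67 on each transgenic array and at most 9.61 on each wild-type array. The bulge list was lower in 13 of 16 members (median -0.18, adjusted p = 9.3e-06, and adjusted p = 0.0021 with an estimated correlation); Fst fell, and Col17a1 (-0.48) and Dkk3 (-0.44), a secreted protein of the Dickkopf family, passed adjusted over the list alone. Nfatc1, a transcription factor of bulge stem cells, was at 0.38, and Cd34 at -0.20. Both lists passed with any 1 of the 6 arrays left out.

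A further 7 lists passed at P23 with the preset correlation. Of 29 dermal matrix genes 27 were lower (median -0.16, camera adjusted p = 9.3e-06, but adjusted p = 0.19 with an estimated correlation), with Col14a1 at -0.40 and Col6a3 at -0.28. Of 21 epidermal differentiation genes 16 were higher (median 0.19, adjusted p = 0.002, and adjusted p = 0.19 with an estimated correlation), with filaggrin (Flg) at 0.59, Krt1 at 0.53 and corneodesmosin (Cdsn) at 0.46. Of 22 immediate early and heat shock genes 16 were higher (median 0.15, adjusted p = 0.002, and adjusted p = 0.17 with an estimated correlation), with Ier3 at 0.49 and Hspa8 at 0.46. Cell cycle genes were lower in 27 of 37 (median -0.10, adjusted p = 0.013, and adjusted p = 0.21 with an estimated correlation), with Cks1b at -0.31 and Cdk1 at -0.29. Cholesterol synthesis genes were higher in 11 of 14 (median 0.18, adjusted p = 0.013, and adjusted p = 0.21 with an estimated correlation). Erythroid genes were higher in 5 of 7 (median 0.19, adjusted p = 0.013, and adjusted p = 0.17 with an estimated correlation), with Alas2 (0.72) and Hba-a1 (0.52) past the threshold adjusted over the list alone. Inner root sheath genes were lower in 7 of 9 (median -0.16, adjusted p = 0.018, and adjusted p = 0.17 with an estimated correlation), with Krt27 (-0.72) past it adjusted over the list alone. With 46.9 added to each signal, which damps dim readings, this list had adjusted p = 0.11. Ptch1, the hedgehog receptor gene, was at -0.40 at 1 probe set and 0.15 at another (adjusted p = 0.634 for the first), and Lmo4 at -0.50 (adjusted p = 0.603).

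The count at P23 was 6, 16 and 2 without wild-type replicates 1, 2 and 3. Without transgenic replicates 1 and 2 it was 4 and 3. It was 17 with quantile normalization and 44 with array weights. In a fit of only these arrays it was 3, all of them lower, so Sprr1a, Krt16, Car12 and Aebp2 did not pass there. With the replicate number as a block it was 1. With that block Sprr1a passed (0.016) and the other 8 genes did not: Gli1 and Fst (0.054), Npnt and Krt16 (0.065), Car12 (0.096), Bnc1 (0.11), Aebp2 (0.13) and Krtap3-1 (0.26). With 46.9 added to each signal Bnc1 (0.061), Krt16 (0.052) and Krtap3-1 (0.14) did not pass. Gli1 passed with any 1 array left out (up to 0.049). The others did not pass in 2 to 5 of 6 runs, and their highest adjusted p without 1 array was 0.064 for Sprr1a and Fst (without wild-type replicate 3), 0.068 for Npnt (transgenic 3), 0.12 for Car12 and 0.18 for Bnc1 (transgenic 2), and 0.21 for Aebp2, 0.22 for Krt16 and 0.53 for Krtap3-1 (wild type 1). The cell cycle list (0.14 without wild-type 2), the cholesterol list (0.48 without wild-type 1), and the inner root sheath and erythroid lists (0.10 without wild-type 3) also did not pass.

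Averaged over the 3 ages, Col17a1, Bnc1, Npnt and Lmo4 were lower in transgenic skin, while the list of 13 basal keratinocyte and hemidesmosome genes had a median of 0.08 (camera adjusted p = 0.96). Col17a1 fell 1.40-fold (log2 change -0.49, SE 0.06, adjusted p = 6.4e-05 in limma), with differences of -0.36, -0.62 and -0.48 at P6, P14 and P23. Bnc1 fell 1.51-fold (-0.59, SE 0.07, adjusted p = 6.4e-05), with -0.66, -0.44 and -0.67. Lmo4 fell 1.39-fold (-0.48, SE 0.09, adjusted p = 0.019), with -0.31, -0.62 and -0.50, and Pdlim4, which encodes a PDZ and LIM domain protein, rose 1.35-fold (0.43, SE 0.08, adjusted p = 0.025). A further 6 genes passed and were chosen after their values were seen. Npnt (-0.65, adjusted p = 0.00056), the arginase gene Arg1 (-0.76, adjusted p = 0.011), Rflnb (-0.44, adjusted p = 0.011), whose product binds filamin, and Nrep (-0.30, adjusted p = 0.041) fell. The nucleoside transporter gene Slc29a1 (0.77, adjusted p = 0.032) and Meg3 (0.95, adjusted p = 0.032) rose, Meg3 with differences of 0.37, 2.48 and 0.01. With a probe set of several genes there were 11, 4 higher and 7 lower, each with the same sign at the 3 ages, and 436 had an unadjusted p under 0.05 against 311 given by chance.

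The bulge list was lower over the 3 ages in 11 of 16 members (median -0.09, camera adjusted p = 0.00048, and adjusted p = 0.0076 with an estimated correlation), with 1 fallen, 15 not past the threshold and 3 lower adjusted over the list alone, namely Col17a1, Fzd2 (-0.35) and Ccn2 (-0.33). At P6 alone the bulge list was not lower (9 of 16 higher, median 0.06, adjusted p = 0.93), so that the average rests on P14 and P23. Of the 9 CLIM and LIM domain factors 1 (Lmo4) fell and 8 did not pass, and the list had adjusted p = 0.65. With the preset correlation 6 more lists passed, none of which did with an estimated correlation. Stress response genes were higher in 11 of 16 (median 0.08, adjusted p = 0.0037, and adjusted p = 0.3 with an estimated correlation), with Krt16 at 0.62, Sprr1a at 0.43 and Krt6b at 0.33. Immediate early genes (17 of 22, median 0.10, adjusted p = 0.011, and 0.3 with an estimated correlation) and epidermal differentiation genes (15 of 21, median 0.06, adjusted p = 0.019, and 0.4 with an estimated correlation) were higher. Dermal matrix genes (23 of 29, median -0.10, adjusted p = 0.0021, and 0.4 with an estimated correlation), hair shaft keratins (9 of 10, median -0.09, adjusted p = 0.019, and 0.4 with an estimated correlation) and inner root sheath genes (7 of 9, median -0.14, adjusted p = 0.019, and 0.3 with an estimated correlation) were lower. Named members were Ogn at -0.36, Tnc at -0.39, Krt32 at -0.27, Krt27 at -0.29 and Krt1 at 0.43, and Dlx2, a regulator of the hair matrix, was at -0.43 (adjusted p = 0.205).

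**Figure D2:**
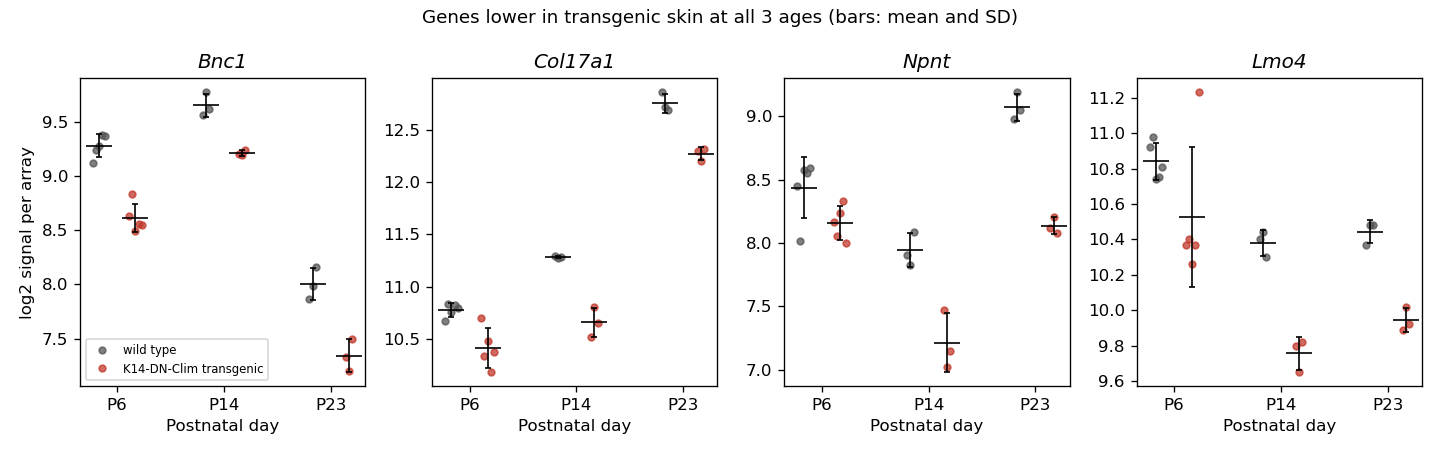
Log2 signal of Bnc1, Col17a1, Npnt and Lmo4 on each of the 22 arrays (points) by age and genotype, with the mean and SD of each group. Over the 3 ages the differences, transgenic minus wild type, were -0.59, -0.49, -0.65 and -0.48.

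The calls of Bnc1, Col17a1, Npnt, Arg1 and Rflnb over the 3 ages passed with any 1 of the 22 arrays left out. Lmo4 had adjusted p = 0.055 without transgenic P14 replicate 2, 0.054 and 0.052 without wild-type P23 replicates 2 and 3 and 0.051 without transgenic P23 replicate 3, and 0.052 with the replicate number as a block. With that block Pdlim4 (0.066), Meg3 (0.13) and Nrep (0.19) did not pass either. Pdlim4 did not pass in 10 of the 22 runs without 1 array, Slc29a1 in 14, Meg3 in 15 and Nrep in 18 (highest adjusted p = 0.07, 0.10, 0.10 and 0.15). The count was 7 without transgenic P6 replicate 1 or 2 or transgenic P23 replicate 3, and 6 without wild-type P23 replicate 2 or 3. With the preset correlation the bulge, stress and immediate early lists passed with any 1 array left out. Of these only the bulge list passed with an estimated correlation. Without transgenic P14 replicate 2, 4 lists passed and the dermal matrix list had 0.13. The hair shaft (up to 0.10), inner root sheath (up to 0.085) and epidermal differentiation (up to 0.06) lists did not pass in 8, 3 and 2 of the 22 runs, nor the inner root sheath list with 46.9 added to each signal (0.054). The differences of the 6211 probe sets were weakly related between ages, with Pearson r across probe sets, which are not independent replicates, of 0.024 for P6 and P14, 0.104 for P6 and P23 and 0.010 for P14 and P23. In 1000 permutations of genotype within age the one-sided p was 0.275, 0.058 and 0.409.

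The difference between genotypes itself changed with age at few genes. For Sft2d1 it was 1.74 higher at P14 than at P6 (log2, SE 0.28, adjusted p = 0.023 in limma), and for Fst it was lower at P23 than at P6 (-1.32, SE 0.22, adjusted p = 0.039); both were chosen after their values were seen. No probe set passed in limma for P23 against P14, with 317 at an unadjusted p under 0.05 against 311 given by chance; for P14 against P6 and P23 against P6 there were 1 each, with 416 and 303. Sft2d1 did not pass in 10 of its 16 runs without 1 array (up to 0.12), nor Fst in 12 of 16 (up to 0.21), and with the replicate number as a block they had 0.093 and 0.21. Among the lists, the genotype difference of the bulge markers was lower at P23 than at P6 (median difference of differences -0.19, camera adjusted p = 0.0012, and adjusted p = 0.025 with an estimated correlation). The genotype difference of the erythroid genes was higher at P23 than at P6 (0.55, adjusted p = 0.00027, and adjusted p = 0.04 with an estimated correlation). For the stress list the genotype difference, not the level, was higher at P23 than at P14 (0.43, adjusted p = 1.3e-06, and adjusted p = 0.072 with an estimated correlation). It was also higher at P23 than at P6 (0.40, adjusted p = 9.5e-06, and adjusted p = 0.057 with an estimated correlation). These contrasts of lists between ages were not run with 1 array left out or under the alternatives of processing.

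Between P6 and P14 genes of the dermal matrix and the cell cycle fell in wild-type skin and inner root sheath genes rose, each list also with an estimated correlation (adjusted p = 0.022 for each). Krt1, the keratin of the suprabasal epidermis, fell 20.5-fold (log2 change -4.36, SE 0.16, adjusted p = 1.74e-14 in limma) from 14.24 ± 0.07 (SD, n = 5) to 9.89 ± 0.08 (SD, n = 3). Filaggrin fell 10.9-fold (Flg, log2 change -3.45, SE 0.17, adjusted p = 3.44e-12), and Casp14 (-2.67), Calm4 (-1.85) and the protease gene Klk8 (-1.48) fell with them. Krt77, another epidermal keratin, rose 4.23-fold (2.08). The small proline-rich Sprr2h rose 12.2-fold (3.61, SE 0.37, adjusted p = 2.74e-07), Sprr2e (1.08), Krt6a (1.11) and the alarmin gene S100a8 (2.02) rose, and Sprr2g fell by 2.59. The imprinted growth regulator Dlk1 fell 5.04-fold (-2.33), and Meg3 fell by 4.15 at 1 probe set and 1.79 at the other. In each of these 13 genes every P14 array lay on one side of every P6 array, which the naming rule required of the largest rises and falls. Of 6211 probe sets 1290 passed, 586 higher and 704 lower, and 207 of them differed over 2-fold.

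Hair genes rose from P6 to P14. Of 10 hair shaft keratins 8 rose, 0 fell and 2 did not pass (8 rose adjusted over the list alone), with Krt84 at 1.42 and Krt86 at 1.23; the list had camera adjusted p = 1.5e-05, and adjusted p = 0.063 with an estimated correlation. Of 11 keratin-associated proteins 7 rose, 1 fell and 3 did not pass (8 and 1 adjusted over the list alone), with Krtap9-1 and Krtap12-1 both at 1.60, and of 9 inner root sheath genes 5 rose and 4 did not pass (5 adjusted over the list alone), with Krt72 at 1.98 and Krt27 at 0.70. Both lists passed either way, with adjusted p = 0.041 and 0.022 with an estimated correlation. Of 16 stress response genes 10 rose, 1 fell and 5 did not pass (13 and 1 adjusted over the list alone; adjusted p = 1.8e-07, and adjusted p = 0.022 with an estimated correlation). Of 21 epidermal differentiation genes 11 fell, 5 rose and 5 did not pass (12 and 5 adjusted over the list alone; adjusted p = 7.1e-05, and adjusted p = 0.079 with an estimated correlation).

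Dermal, dividing and vascular genes fell over the same interval. Of 29 dermal matrix genes 19 fell, 0 rose and 10 did not pass (23 fell adjusted over the list alone), with Col6a2 at -1.68, lumican (Lum) at -1.51 and Col6a3 at -1.34 (camera adjusted p = 5.8e-15, and adjusted p = 0.022 with an estimated correlation). Of 37 cell cycle genes 22 fell and 15 did not pass (24 adjusted over the list alone), with Kif2c at -0.79 and Cks1b at -0.68 (adjusted p = 2.9e-09, and adjusted p = 0.022 with an estimated correlation). Of 13 endothelial genes 5 fell and 8 did not pass (6 fell and 1 rose adjusted over the list alone), with the tight junction gene Cldn5 at -0.89 and Cdh5 at -0.77 (adjusted p = 0.016, and adjusted p = 0.041 with an estimated correlation). Of 16 adipocyte genes 9 fell and 7 did not pass (10 adjusted over the list alone), with Car3 at -1.68, adiponectin (Adipoq) at -1.48 and Lpl at -1.18 (adjusted p = 0.00017, and adjusted p = 0.063 with an estimated correlation). The mast cell proteases Cma1 (-1.45) and Cpa3 (-1.33) fell, with 3 of 5 members fallen (adjusted p = 0.033, and adjusted p = 0.19 with an estimated correlation). The dermal papilla gene Vcan fell by 1.62, and 2 of 5 members fell (adjusted p = 0.033, and adjusted p = 0.085 with an estimated correlation). Of 9 CLIM and LIM domain factors 4 fell, 0 rose and 5 did not pass (4 adjusted over the list alone; adjusted p = 0.033, and adjusted p = 0.068 with an estimated correlation). These were Lmo1 (-1.03), Ldb1 (-0.59), Lmo4 (-0.46) and the CLIM-binding Ssbp2 (-0.33).

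Muscle and immune genes changed in both directions. Among 26 skeletal muscle genes 4 rose, 1 fell and 21 did not pass (adjusted over the list alone, also 4 and 1; camera adjusted p = 0.033, and adjusted p = 0.41 with an estimated correlation). The adult fast myosins Myh4 (3.61) and Myh1 (1.92) rose, and the perinatal Myh8 fell by 2.19. Of 22 immediate early and heat shock genes 4 rose (adjusted p = 0.033, and adjusted p = 0.19 with an estimated correlation). Of 21 macrophage and antigen presentation genes 5 rose and 5 fell (adjusted p = 0.089), with the chemokine gene Ccl8 at 1.79 and H2-Aa of MHC class II at 0.97. Col17a1 rose by 0.50, and the bulge list, with 4 risen and 3 fallen of 16, had adjusted p = 0.73. Among the 5 Wnt targets Lef1 fell and 4 did not pass.

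The count from P6 to P14 was 817 with the sex class as a covariate, and Cdh5 (0.074), H2-Aa (0.09), Ldb1 (0.051), Lmo4 (0.46) and Ssbp2 (0.29) then did not pass, with log2 changes of -0.65, 0.64, -0.49, -0.22 and -0.22. The class with both Xist and Eif2s3y signals held 4 of the 5 wild-type P6 arrays and no later one. This covariate therefore nearly follows age, and these losses do not show a dependence on sex. Lmo4 (without wild-type P6 replicate 1 or 2 or any P14 array, up to 0.11) and Ssbp2 (without P6 replicate 2 or 3 or P14 replicate 2 or 3, up to 0.10) also depended on single arrays. So did the skeletal muscle (0.15), mast cell (0.061) and immediate early (0.061) lists, each without P14 replicate 2. With the P6 arrays numbered 1 to 3 and 4 to 5 as batches, chosen after seeing the data, the CLIM and LIM domain (0.054), skeletal muscle (0.07) and dermal papilla (0.055) lists and Lmo4 (0.066) did not pass.

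From P14 to P23 wild-type skin lost hair transcripts and gained those of dermis, fat, muscle and macrophages. Krtap19-5 fell by 10.56 (log2, SE 0.16, adjusted p = 9.6e-23 in limma), Krtap9-1 by 10.49, the inner root sheath keratin Krt25 by 10.25 and Crym, a thyroid hormone binding protein, by 9.55. All 11 keratin-associated proteins and all 10 hair shaft keratins fell, with Krt83 at -8.88 and Krt31 at -8.19. Of 9 inner root sheath genes 8 fell and 1 did not pass, with Padi3 at -7.57 and Krt72 at -6.56. These 3 lists had adjusted p = 0.00066, 0.0046 and 0.00066 with an estimated correlation. Of 19 regulators of the hair matrix 15 fell, 0 rose and 4 did not pass (adjusted p = 0.0082 with an estimated correlation), with the homeobox genes Msx2 at -6.88 and Dlx3 at -3.77 and Lef1 at -1.42. At P23 the mean signals of Krtap19-5, Krtap9-1, Krt25, Crym, Krt83, Padi3 and Msx2 lay below the 25th percentile of the signals, 46.9, so that the sizes of their falls are set by dim readings. With 46.9 added to each signal the changes were -7.15, -9.30, -8.59, -6.87, -7.72, -5.97 and -4.91. In total 3364 of 6211 probe sets passed, 1680 higher and 1684 lower, and 1197 differed over 2-fold.

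Cell cycle and stress response genes fell along with the hair genes. Of 37 cell cycle genes 26 fell, 0 rose and 11 did not pass (26 adjusted over the list alone; adjusted p = 0.021 with an estimated correlation), with Cdc20 at -2.01, Mki67 at -1.95 and Cdk1 at -1.63. Of 16 stress response genes 13 fell, 1 rose and 2 did not pass (adjusted over the list alone, also 13 and 1; adjusted p = 0.036 with an estimated correlation), with Sprr2h at -6.82, Sprr1a at -4.20 and Krt17 at -2.46. Of 8 melanocyte genes 6 fell, 1 rose and 1 did not pass (camera adjusted p = 0.0057, and adjusted p = 0.17 with an estimated correlation), with the melanosome gene Pmel at -2.81 and Dct at -1.66. Of 7 erythroid genes 5 fell and 2 did not pass (adjusted p = 0.0087, and adjusted p = 0.065 with an estimated correlation), with Alas2 at -1.12.

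Genes of the dermis, vessels, fat and muscle rose. Of 29 dermal matrix genes 25 rose, 1 fell and 3 did not pass (25 and 1 adjusted over the list alone; adjusted p = 0.036 with an estimated correlation), with Serpinf1 at 2.71, lumican at 2.31 and decorin (Dcn) at 1.38. Of 26 skeletal muscle genes 23 rose and 3 fell (adjusted p = 0.024 with an estimated correlation), with Pygm at 3.27, the calcium release channel Ryr1 at 3.14 and Atp2a1 at 1.70. Of 16 adipocyte genes 13 rose and 3 did not pass (14 rose and 1 fell adjusted over the list alone; adjusted p = 0.023 with an estimated correlation), with Car3 at 2.33 and Adipoq at 2.09. Of 13 endothelial genes 9 rose and 4 did not pass (9 adjusted over the list alone; adjusted p = 0.019 with an estimated correlation), with Emcn at 1.39 and Cdh5 at 1.16. Of 5 dermal papilla genes 4 rose and 1 fell (camera adjusted p = 0.049, and adjusted p = 0.11 with an estimated correlation), with Igfbp3 at 2.82; without P14 replicate 1 the adjusted p was 0.051 and without P23 replicate 2 it was 0.05. Of 6 Schwann cell genes 5 rose and 1 fell (adjusted p = 0.027, and adjusted p = 0.11 with an estimated correlation), with the myelin gene Pmp22 at 2.23.

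Macrophage and bulge markers rose as well. Of 21 macrophage and antigen presentation genes 17 rose, 0 fell and 4 did not pass (17 adjusted over the list alone; adjusted p = 0.021 with an estimated correlation), with lysozyme (Lyz2) at 2.86, the complement gene C1qa at 2.03 and Ctss at 2.01. Of 5 mast cell genes 3 rose and 2 did not pass (camera adjusted p = 0.021, and adjusted p = 0.13 with an estimated correlation), with Cpa3 at 2.23. Thy1, the 1 tested T cell gene, rose by 1.74. Of 16 bulge markers 10 rose, 3 fell and 3 did not pass (adjusted over the list alone, also 10 and 3; adjusted p = 0.036 with an estimated correlation), with Cd34 at 2.02, Ccn2 at 1.63 and Col17a1 at 1.48. Aldh1a1, a retinoic acid synthesizing enzyme, rose 13.2-fold (3.73), and Meg3 rose by 3.23 at 1 probe set and 1.42 at the other.

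Further lists did not pass as lists from P14 to P23 but held members that changed. Of 11 clock genes 5 rose and 1 fell (camera adjusted p = 0.18), with Nr1d2 at 2.36, Per1 at 1.11 and Cry1 at -0.71. Of 21 epidermal differentiation genes 12 rose and 6 fell (adjusted p = 0.13), with Krt1 at 2.58. Of 13 basal keratinocyte genes 7 rose and 3 fell (adjusted p = 0.2). Of 9 CLIM and LIM domain factors 2 rose and 2 fell (adjusted p = 1.0), with Ssbp2 at 0.85 and Rlim, a ubiquitin ligase that binds CLIM, at -0.95. Of 7 sebaceous genes 3 rose (adjusted p = 0.13), and of 14 cholesterol genes 1 rose and 3 fell (adjusted p = 0.3). All 47 genes named for this interval, including those of other paragraphs, passed with any 1 array left out and under each alternative that kept them in the test.

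**Figure D3:**
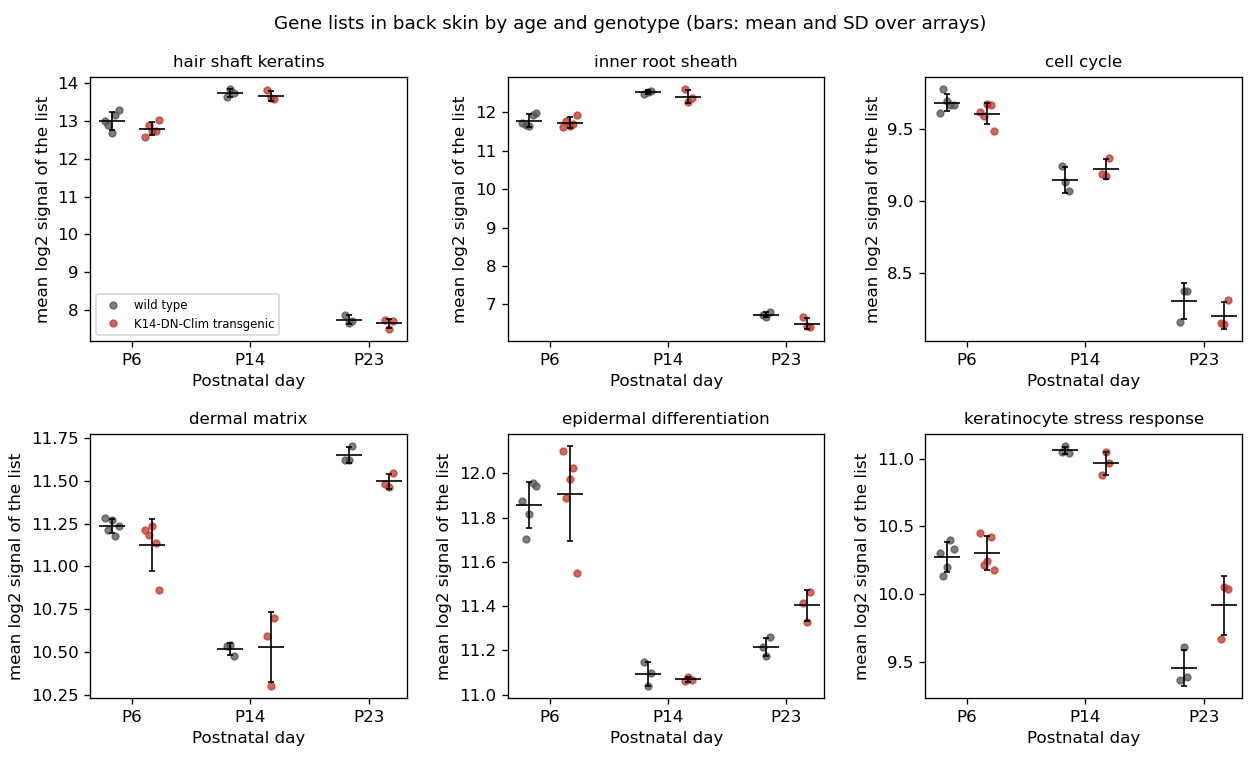
Mean log2 signal of 6 gene lists on each array (points) at P6, P14 and P23 in wild-type and transgenic skin, with the mean and SD of each group. Hair shaft keratins fell from P14 to P23 by a median of 6.10 in wild type, and the stress response list fell by 1.22.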

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

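The sample gaps and the differences between ages below were computed by rules fixed before the data were examined. The genes searched for gaps were those named in the text, some of them chosen after their values were seen. Among the 5 arrays of each P6 group, 78 genes and 25 list means were searched for an array far from the others. Of 206 tests 9 were past Dixon's limit of 0.71, where chance gives about 1 in 20, or 10.3, so their number is no more than chance gives. That rate may not hold for genes picked by their values. Transgenic P6 replicate 5 was the array apart in 4 of the 9. It also lay apart over all probe sets, at 33.7 on the component that held 20.2% of the within-group variance, against -10.7 to 3.3 for the other 21 arrays. Its mean correlation with its group was 0.923.

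Lmo4 was at a log2 signal of 11.23 on transgenic P6 replicate 5 and 10.26 to 10.40 on the other 4 (gap over range 0.853). Casp14, a caspase of cornification, was at 9.11 there against 10.90 to 11.47 (0.759). The mean of the cholesterol synthesis list was 9.58 there against 9.91 to 10.01 (0.760), and that of the dermal matrix list 10.86 against 11.13 to 11.23 (0.734). Krt6a was at 13.26 on transgenic P6 replicate 1 against 12.69 to 12.83 (0.766). In wild type, Npnt was at 8.02 on replicate 2 against 8.45 to 8.59 (0.761), and Krtap5-4 at 10.46 on replicate 3 against 10.97 to 11.12 (0.776). Krtap12-1 was at 9.22 on replicate 4 against 9.88 to 10.02 (0.833), and the mean of the macrophage and antigen presentation list was 8.84 on replicate 3 against 8.61 to 8.68 (0.728).

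The genotype difference itself differed between ages for 2 genes and 2 lists. For Sft2d1 it was 1.74 higher at P14 than at P6 (log2, limma adjusted p = 0.023), and for Fst it was -1.32 at P23 relative to P6 (adjusted p = 0.039). For the bulge list the median of these differences between P23 and P6 was -0.19, with 12 of 16 members lower, and for the erythroid list it was 0.55, with 7 of 7 members higher. Both lists passed with the preset and with an estimated correlation. Neither was run for this contrast with 1 array left out, under the alternatives of processing or in the splits of the arrays. No explanation was tested for any of these.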

How the results depend on the processing

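Runs on batches of the P6 arrays were chosen after seeing the data; the other alternatives were fixed in advance. The calls between wild-type ages were the most stable: of the genes named, 47 of 47 from P14 to P23 and 37 of 42 from P6 to P14 passed in each alternative that kept them and without any 1 array, against 5 of 10 over the 3 ages and 0 of 2, 0 of 3 and 0 of 9 at P6, P14 and P23. No called gene changed direction. Where a call or count moved, the cause was not tested. The median log2 difference of all tested probe sets was at most 0.069 in size in any comparison and alternative. That value came with the stricter filter, in wild type from P14 to P23.

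For transgenic against wild type at P6 (2 probe sets, in limma) the count was 5 with no filter, 0 with the stricter filter, 1 with 1 probe set per gene, 4 with the replicate block, 0 with the sex class, 1 with only the groups compared and 5 in arrays 1 to 3 or 4 to 5 alone, and 2 to 5 without 1 array. At P14 (4) it was 13 with no filter or with array weights, 8 without the trend, 1 with only the groups compared, and 0 to 9 without 1 array. At P23 (10) it was 17 with quantile normalization, 2 with the stricter filter, 44 with array weights, 1 with the replicate block, 3 with only the groups compared, and 2 to 16 without 1 array. Over the 3 ages (11) it was 6 with the stricter filter, 26 with array weights, and 6 to 16 without 1 array. In wild type from P6 to P14 (1290) it was 830 with the stricter filter, 817 with the sex class and 861 to 1237 without 1 array, and from P14 to P23 (3364) 1894 with the stricter filter and 2970 to 3071 without 1 array.

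For the genotype difference at P14 against that at P6 (1) the count was 0 without the trend, with the replicate block or with only the groups compared, and 0 to 2 without 1 array. At P23 against P14 (0) it was 1 with quantile normalization or only the groups compared, 20 with array weights, and 0 to 2 without 1 array. At P23 against P6 (1) it was 5 with quantile normalization, 3 without the trend or with 1 probe set per gene, 4 with array weights, 2 with only the groups compared, 0 with no filter, the stricter filter, the replicate block or the sex class, and 0 to 4 without 1 array.

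Of the gene lists at P6 (8), 0 passed with an estimated correlation or by fry, 5 with no filter, 1 in arrays 1 to 3, 3 in arrays 4 and 5, and 1 to 7 without 1 array. At P14 (2), 0 passed with an estimated correlation, 1 with quantile normalization or no filter, 4 with the replicate block, and 0 to 4 without 1 array. At P23 (9), 2 passed with an estimated correlation or by fry, and 6 to 10 without 1 array. Over the 3 ages (7) it was 1 with either, and 4 to 9 without 1 array. In wild type from P6 to P14 (14), 6 passed with an estimated correlation and 11 to 15 without 1 array, and from P14 to P23 (17), 16 to 17 without 1 array.

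Quantile normalization also moved the split of higher and lower calls, from 3 and 1 to 3 and 2 at P14, from 4 and 7 to 7 and 8 over the 3 ages and, at P23 against P6, from 0 and 1 to 3 and 2; of the lists at P6 it made 2 higher and 6 lower, against 3 and 5. With each array shifted to the same median the 1289 calls from P6 to P14 were 648 higher and 641 lower, against 586 and 704, and those from P14 to P23 were 1526 and 1855, against 1680 and 1684. Of the lists that passed with all arrays, 1 reversed its sign: epidermal differentiation at P6, in arrays 4 and 5, without passing there (camera adjusted p = 0.67). The other reversed signs concerned genes not past the threshold with all arrays. At P6 they were Lmo4 in arrays 4 and 5 (0.02) and Cd34 without wild-type replicate 4 (-0.01, range without 1 array -0.01 to 0.26). At P14 Ldb1 reversed without transgenic replicate 2 (0.06) or 3 (0.05, range -0.27 to 0.06). At P23 Ldb1 reversed without wild-type replicate 2 (-0.02, range -0.02 to 0.16). Ldb2 reversed at P23 without wild-type replicate 2 (0.09) or transgenic replicate 3 (0.10, range -0.12 to 0.10). The cause was not tested. The replicate numbers were not taken to pair the arrays, since the correlation of the deviations of same-numbered arrays was -0.047 to 0.249 over 11 pairs and over 0.1 in only 4. As a hint from the data, 6 of the 11 wild-type arrays matched their own number best against 3 by chance. All 3 at P23 did (0.136, 0.056 and 0.249), where the arrays of each number were also of one sex, and there the block left 1 of the 10 calls. The replicate block ended 15 of 115 gene calls and 4 of 57 list calls.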

Other observations

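All tests in this part were chosen after the results they bear on were seen, the splits of the arrays included.

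The keratinocyte stress response list was higher in transgenic skin at P23 by a median of 0.43 (log2). Growing follicles left in the transgenic samples would bring hair transcripts, since in wild type from P14 to P23 the 21 hair keratins and keratin-associated proteins changed by a median of -6.92 and the stress list by -1.22. At P23 those 21 genes had a median difference of -0.11 (quartiles -0.38 and 0.07), which argues against this for follicles that make a hair shaft. Parts of the follicle without these genes were not tested as a source. A larger share of epidermis would raise basal keratinocyte genes alike, but these 13 had a median of -0.03 (quartiles -0.12 and 0.02), which argues against it as the whole of the 0.43, and after quantile normalization the stress list stood at 0.49 (adjusted p = 0.0044 with an estimated correlation). Epidermal differentiation genes (16 of 21 higher) and dermal matrix genes (27 of 29 lower; both adjusted p = 0.19 with an estimated correlation) moved as a larger share would have them, so a part played by the share is left open; 16 of 22 immediate early and heat shock genes were also higher (adjusted p = 0.17 with an estimated correlation).

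Bnc1, Col17a1, Npnt and Lmo4 were lower in transgenic skin over the 3 ages by -0.48 to -0.65. The 4 were picked from the genes that passed as lower. Fewer basal keratinocytes would lower the genes of the basal keratinocyte and hemidesmosome list too. Of the 4 that list holds only Col17a1, and its other 12 genes had a median of 0.08 (quartiles -0.03 and 0.12). After quantile normalization the highest adjusted p of the 4 genes was 0.010, and with the sex class as a covariate it was 0.042, in limma. The tables argue against these 3 explanations, the first of them for basal keratinocytes as a whole. No other was tested, including a loss of only some basal cells.

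Meg3 was higher in transgenic skin at P14 at 1 of its 2 probe sets. The other probe set gave 0.29 (SE 0.17, adjusted p = 0.83), so that a signal read by only 1 of the probe sets is a candidate explanation. In wild type the first probe set was at 11.82, 7.68 ± 1.12 (SD, n = 3) and 10.91 at P6, P14 and P23, and the second at 11.01, 9.22 and 10.64, so the wild-type level at P14 was the low one at both. A single array or the scaling does not account for the difference, since it was at least 2.15 without any 1 array and 2.49 after quantile normalization. The call at the first probe set itself had adjusted p = 0.057 without wild-type replicate 3 and 0.22 in a fit of only the groups compared.

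Some P6 arrays carried transcripts of both sexes. Xist and the Y-linked Eif2s3y were together above a log2 signal of 6 on 6 of the 10 P6 arrays, 4 of them wild type and 2 transgenic, and on 0 of the 12 later arrays (Fisher's exact test, two-sided p = 0.00281). The Eif2s3y probe set was dim (28.8 as a percentile of mean signal). On these 6 arrays the Y-linked Uty read 4.11 to 5.7 (log2). It read 5.29 on an array classed as female and 5.05 on one classed as male (transgenic P14 replicates 2 and 1). The Y-linked Kdm5d read 3.55 to 4.78 on the 6 arrays and 5.91 on an array classed as female (transgenic P14 replicate 3). Neither settles whether Y-linked transcripts were present. The test restates the pattern that prompted it, so it does not decide whether these samples hold RNA of several animals, and the design text speaks of separate mice.

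Probe sets of Pdxdc1 moved in opposite directions between arrays of one group. Over the 22 arrays the deviations of 2 of its probe sets from their group means had Pearson r = -0.68, and the other 2 pairs had r = -0.66 and 0.92. The gene was chosen for this pattern, so these values do not decide whether a sequence difference between the parent strains accounts for it.

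The P6 arrays numbered 4 and 5 differed from those numbered 1 to 3 at 345 probe sets (146 higher, 199 lower, limma with genotype in the fit), with the peptidase gene Anpep at -1.14, Igfbp4 at -0.95, Thy1 at -1.09, Krt10 at 0.74 and Ctnnb1 at 0.44. All 8 melanocyte genes were lower in 4 and 5 (median -0.38, camera adjusted p = 0.012, and adjusted p = 0.68 with an estimated correlation), and 18 of 22 immediate early and heat shock genes were higher (median 0.19, adjusted p = 0.012, and adjusted p = 0.045 with an estimated correlation). Immediate early, hair shaft and dermal matrix lists also passed between genotypes at P6 with the preset correlation, but none of them did with an estimated one. In 4 and 5 hair shaft keratins were higher in 9 of 10 (median 0.31, adjusted p = 0.015) and dermal matrix genes lower in 23 of 29 (median -0.12, adjusted p = 0.034), each with adjusted p = 0.68 with an estimated correlation.

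Splits of the arrays gave the following, with the real split counted among them in each number of splits. At P6, 14 of 100 splits gave at least the real 2 probe sets and the highest of the others 73, so chance cannot be excluded, and the split with 73 parted 9 of the 10 arrays into those numbered 1 to 3 and those numbered 4 and 5. This points to a structure of the samples. The count was 4 with the replicate number as a block, 3 with the batch term, and 5 within arrays 1 to 3 and 5 within arrays 4 and 5. For the lists at P6, 1 of 100 splits gave at least the real 8 (highest other 5), a share under 0.05. Over the 3 ages the share was under 0.05 for the 11 probe sets (1 of 100, highest other 3) but not for the 7 lists (6 of 100, highest other 9). For wild type from P6 to P14 it was under 0.05 for the 1290 probe sets (1 of 56, highest other 218) and the 14 lists (1 of 56, highest other 12). It was not under 0.05 for the genotype differences at P14 against P6 (13 of 100 with at least 1, highest other 4) and at P23 against P6 (21 of 100 with at least 1, highest other 2). At P23 against P14 the real count was 0, so that all 100 of 100 splits had to reach it and decide nothing (highest other 7).

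Comparisons of 3 arrays with 3 have 10 splits, the real one included, too few for a share under 0.05. The real split is also counted in the numbers of splits below. At P14 the real count of probe sets was 4 and the highest other 4 (2 splits as large), and of lists 2 and 7 (7 splits). At P23 they were 10 and 3 (1 split) for probe sets and 9 and 7 (1 split) for lists. From P14 to P23 in wild type they were 3364 and 1 (1 split) for probe sets and 17 and 17 (3 splits) for lists.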
